A study of Mus musculus with 6 samples.

How the data were processed

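RNA sequencing was compared between lenses of mouse embryos at E15.5 from 2 groups of 3 libraries each. The conditional knockout (cKO) group carried floxed alleles of Itgb1, which encodes β1-integrin, and the MLR10 Cre transgene, which is active in lens cells, on a mixed strain background, with 30 lenses pooled per replicate. The wild-type group was C57Bl/6, with 75 lenses pooled per replicate, and its records repeat samples of an earlier series. Per the labels' protocols, RNA was isolated with a column kit, poly(A) RNA was selected, and libraries were made with a TruSeq RNA v2 kit and read single-end on an Illumina instrument. That kit does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart.

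Each deposited file lists 41128 features with CPM (reads divided by all reads counted over the listed features and scaled to a sum of 1000000) and RPKM (CPM per kilobase of gene length), both made by the authors, per the file headers. The submitters' processing notes name edgeR and the genome build GRCm38. The aligner, the counting program, the annotation release and the handling of reads that match several places are not given in the sources used here. Every CPM value was a whole multiple of the value of 1 read, within 0.02 reads, in 100% of values of each library, so whole reads were recovered by division. The recovered totals were 20036554, 20214477 and 28095318 reads in cKO replicates 1, 2 and 3 and 11531139, 11407157 and 10023049 in wild-type replicates 1, 2 and 3. At these depths 1 read was worth 0.0356 to 0.0998 CPM, so genes near 1 CPM rest on few reads in wild type. Deposited RPKM values were used only to recover gene lengths for the length correction.

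Ensembl identifiers were given for 38391 features, of which 37667 were found in GENCODE M21 (GRCm38), the source of all coordinates. Features with no Ensembl identifier took 0.19% to 0.21% of the reads of a library. Symbols turned into dates by a spreadsheet were restored by identifier for 27 features. Lim2, Hbb-b1, Hbb-b2, Ahsp and Entpd4b, which are members of the gene lists, were not analysed here.

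The planned test for counts was edgeR's quasi-likelihood test, with limma as the planned test for normalized values. Because the deposited values were CPM, the second was used as the main test: limma-trend on log2(CPM + 1), with robust empirical Bayes moderation and group as the only term, on the genes with at least 1 CPM in at least 3 libraries. Fold changes are therefore on the log2(CPM + 1) scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p given for a gene comes from limma. Gene lists, fixed before the data were examined, numbered 31, and the 26 with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with camera at an estimated correlation, and with fry, each adjusted over the lists. Named genes were chosen by a rule fixed before the data were examined. The rule takes Itgb1, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 10 CPM and groups that do not overlap (leaving out gene models without a proper name), up to 4 members of each list with the smallest adjusted p, and 20 further genes fixed by name, of which 1 is not reported here. Members of lists outside this rule are named as examples, chosen after their values were seen.

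The alternatives were other scalings (RLE size factors, TMM, TMM without crystallins), no filter on low values or a mean of at least 5 CPM, a pseudocount of 0.1, the replicate number as a block, correction for GC content and gene length, limma-voom, DESeq2 and edgeR on the recovered reads, and leaving out each library. Scaling by library size alone, also listed beforehand, is what the deposited CPM already holds. Added after seeing the data were edgeR on recovered reads, TMM-scaled CPM, reads thinned to 10023049 per library, leaving out chromosome 8, and leaving out genes that share at least 10% of their 32-base words (1 in 8 words sampled) with transcripts of another gene. On recovered reads, edgeR called 2433 genes higher and 2453 lower.

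The main test was tested on simulated counts drawn for the comparison of cKO with wild type over 11834 genes. It recovered 82% of 100 genes changed 1.5-fold and 99% of 100 genes changed 2-fold, and 14 of its 195 calls (7.2%) were false. Far fewer genes changed in the simulation than the 36.9% called in the real data, and the lowest genes were not among those changed. These shares therefore need not hold for the real comparison or for low genes. The set test recovered a raised set and called 0 of 20 unchanged sets. The simulated genes were drawn independently, whereas estimated correlations within real lists were as high as 0.662 in cell cycle and 0.736 in mitochondrially encoded genes. The simulation therefore does not show how the set test behaves on correlated lists. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Strain background, the Cre transgene, number of pooled lenses and series of origin all differ between the groups in the same way as Itgb1 genotype. No model can tell these apart. Sequencing depth differs in the same way, but could be equalised by thinning reads. The thinned libraries gave 3936 called genes. Of these, 3803 were among the 4403 called by the main test, all in the same direction, which argues against depth as the source of most calls.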

Results

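The transcriptomes of mouse lenses at embryonic stage E15.5 with a conditional knockout of Itgb1, the gene of β1-integrin, were compared with those of wild-type lenses to ask which genes differ. Integrins are heterodimeric receptors that join cells to the extracellular matrix, and β1 is the partner of many α subunits. Each group held 3 biological replicates, each a pool of 30 cKO or 75 wild-type lenses. The libraries held 20036554 to 28095318 counted reads in cKO and 10023049 to 11531139 in wild type. Crystallin transcripts took 29.8% to 35.0% of reads in cKO and 31.6% to 34.8% in wild type. Correlations of log2(CPM + 1) across genes were 0.992 to 0.996 between replicates of a group and 0.971 to 0.976 between groups. Replicates differed by more than counting noise, with chi-square values per degree of freedom of 4.25 to 18.7, so no library was counted as a repeat of another.

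Itgb1 itself (ENSMUSG00000025809; GRCm38 chromosome 8, 128685654 to 128733200, plus strand, protein coding) fell from 425 ± 22.97 CPM in wild type to 258 ± 19.8 CPM in cKO (SD, n = 3 each). Its log2 fold change was -0.72 (SE 0.077, adjusted p = 1.63e-05 by limma), and the groups did not overlap. The values count reads over the whole gene, and the floxed part is not given in the sources used here, so reads from outside the deleted part are included and the residual level does not measure the remaining protein. Of the 15 integrin subunits tested, 4 were higher and 3 lower in cKO (5 and 4 adjusted over the list alone), and edgeR called 5 lower. Itgb8, a β subunit that pairs with αv, rose from 13.04 ± 3.81 to 65.3 ± 2.95 CPM (log2 fold change 2.28, adjusted p = 7.12e-06). Itga4 rose by 0.71 on the log2 scale, whereas Itga3, an α subunit of laminin receptors, had a log2 fold change of -0.95 and Itgb5 of -0.27. The Itgb5 call was lost without cKO replicate 1 or 2 or wild-type replicate 2 or 3. Itga6 (-0.22, adjusted p = 0.0675) and Itgav (0.12, adjusted p = 0.253) did not pass the test, and Itga6 did pass it with TMM or RLE scaling. The list as a whole did not pass the set test (adjusted p = 0.875). Focal adhesion adaptors went both ways, with 4 of 24 higher and 4 lower (4 and 4 adjusted over the list alone; set test adjusted p = 0.875). The lower count was 7 with RLE or TMM scaling, limma-voom, DESeq2 and edgeR, and the higher count was 2 without cKO replicate 2 or 3 or wild-type replicate 1 or 2. Vcl, which encodes vinculin, rose by 0.81, with 25% of its words shared, while Parva (-0.45), Bcar1 (-0.30) and Tns3 (-0.38) fell.

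**Figure D1:**
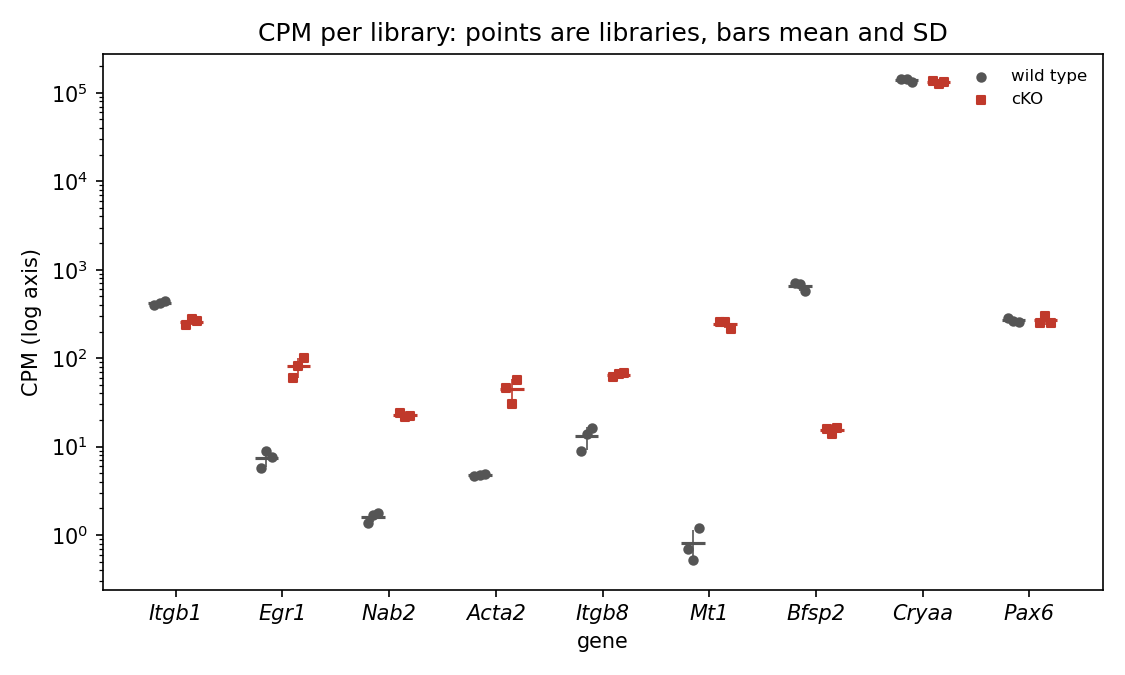
CPM of 9 genes (log axis) in each of the 3 wild-type and 3 cKO libraries, with horizontal bars for the mean and vertical bars for the SD. Itgb1 was 258 CPM in cKO and 425 CPM in wild type, Egr1, Nab2, Acta2, Itgb8 and Mt1 lay higher in every cKO library, Bfsp2 lay lower, and Cryaa and Pax6 did not pass the test.

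Across the 11941 genes tested, 2499 were higher and 1904 lower in cKO lenses, together 36.9% of the genes. With correction for GC content and gene length the split turned to 1972 higher and 2252 lower. Other scalings evened it, to 2407 and 2375 with RLE, 2413 and 2363 with TMM, and 2433 and 2453 with edgeR. The excess of higher genes therefore depended on the scaling. Changes of at least 2-fold were called for 195 genes higher and 99 lower, whereas edgeR on recovered reads called 427 and 212. The first principal component held 73% of the variance. The groups did not overlap in 5744 genes (48.1%), against the 10% that chance gives for 3 against 3 libraries. The median log2 fold change over all tested genes was 0.03.

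The strongest rise was that of Mt1 (ENSMUSG00000031765; chromosome 8, 94179082 to 94180327, plus strand), a metallothionein, from 0.806 ± 0.349 to 242 ± 22.1 CPM (log2 fold change 7.08, SE 0.13, adjusted p = 2.50e-13). The neighbouring gene Mt2 was at 0.329 CPM in cKO and 0.212 CPM in wild type. The Cre transgene and the strain differ between the groups in the same way as genotype, so the rise of Mt1 cannot be assigned to loss of Itgb1. The gene model Gm26825, left out by the naming rule, was at 5.69. Among the genes that the rule admits, Fgf12, a member of the fibroblast growth factor homologous family, followed at 4.03. Nmb, which encodes the peptide neuromedin B, was at 3.68. Scfd2 (3.05), Bend6 (2.79) and Atp10d (2.52) rose as well. The strongest fall was that of Bfsp2 (ENSMUSG00000032556; chromosome 9, 103424924 to 103480420, minus strand), which encodes a lens-specific beaded filament protein. It fell from 653 ± 73.6 to 15.3 ± 1.37 CPM (log2 fold change -5.32, SE 0.094, adjusted p = 2.50e-13). The ribosomal protein genes Rpl35a (-4.14) and Rpl29 (-3.81) fell, as did Abca13 (-4.04), Csmd2 (-3.12), Upp1 (-3.05), Apobec3 (-2.89) and Ccdc85c (-2.30). Myo7a (-2.52) and Ankrd34c (-2.46) passed the test with wider spread, and both lost their call without wild-type replicate 3, Myo7a also without cKO replicate 2 or wild-type replicate 1. Shared sequence can make some of these values uncertain, since 39.9% of the words of Rpl29, 15.3% of those of Nmb, 12.9% of those of Apobec3 and 10.4% of those of Bfsp2 occur in transcripts of other genes. Copies here are listed genes that hold at least 10% of a gene's words. Bfsp2 fell by 638 CPM while its 1 copy changed by 0.012 CPM, and Rpl29 fell by 28.2 CPM while its 17 copies rose by 4.38 CPM. The 1 copy of Nmb rose by 7.80 CPM as Nmb rose by 37.0 CPM, and Apobec3 had 0 copies to check. For Bfsp2, Nmb and Rpl29 these values argue against reads moved to such copies as the whole source. Bfsp2 is also a member of the list of strain-variable genes, and the strain differs between the groups.

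**Figure D2:**
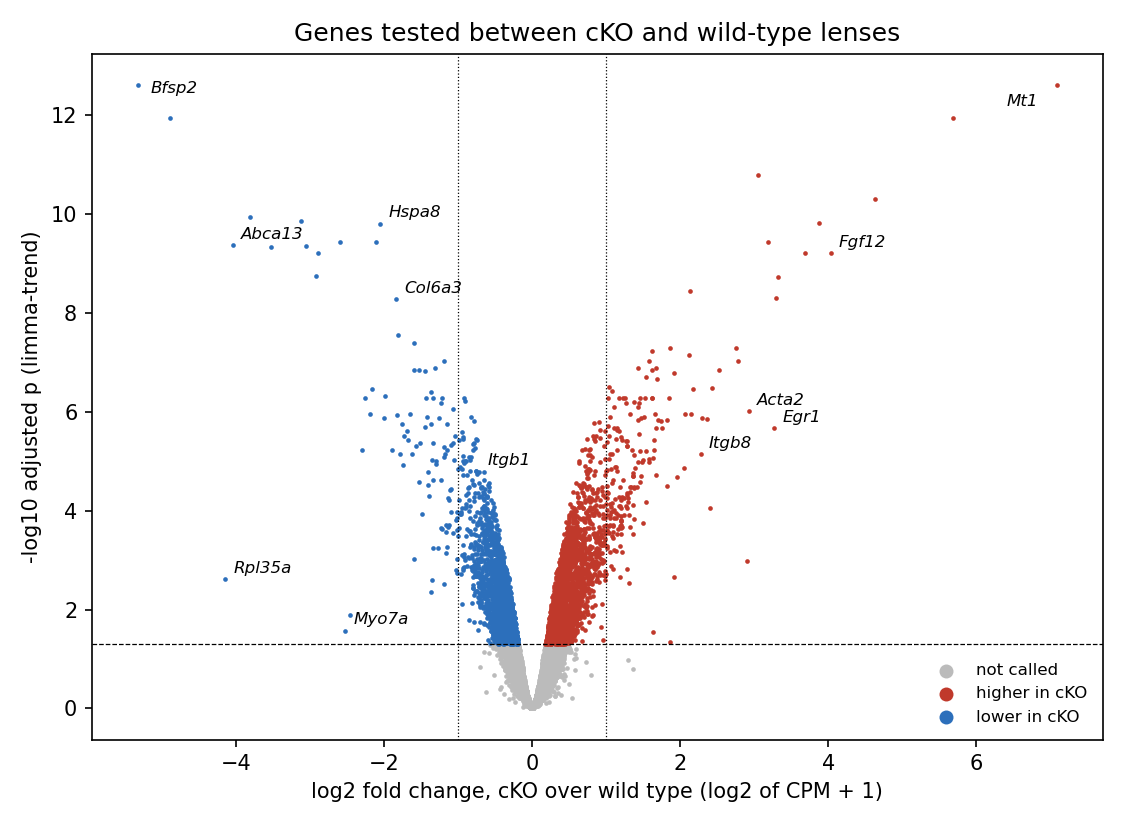
Each point is a gene, with the log2 fold change of cKO over wild type on the x axis and -log10 of limma's adjusted p on the y axis. The dashed line marks an adjusted p of 0.05 and the dotted lines a change of 2-fold. Above the dashed line lie 2499 genes higher and 1904 lower in cKO, with Mt1 and Bfsp2 at the far ends.

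Immediate early genes, which are transcribed within minutes of a stimulus, and their regulators rose together, with 20 of 24 higher and 1 lower (20 and 1 adjusted over the list alone). Egr1 (ENSMUSG00000038418; chromosome 18, 34859823 to 34864984), a zinc finger transcription factor, rose from 7.45 ± 1.57 to 81.0 ± 20.6 CPM (log2 fold change 3.27, SE 0.19, adjusted p = 2.14e-06). Nab2 and Nab1, which encode corepressors that bind EGR proteins, rose by 3.18 and 1.45, although 37.9% of the words of Nab2 are shared with other genes. Fos (1.82), Klf4 (1.71) and Atf3 (1.01) rose too, and Myc fell by 0.72. The list passed the set test (adjusted p = 6.14e-07), but not with an estimated correlation (adjusted p = 0.324 with an estimated correlation), and 13 of the 14 members tested were higher when a mean of at least 5 CPM was asked for. In the same libraries 12 of 15 endothelial and 10 of 12 macrophage markers were also higher, and pericyte markers had 4 of 6 higher and 1 lower.

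Cell cycle genes were lower in cKO, with 26 of 34 lower and 0 higher (28 and 0 adjusted over the list alone), and a median log2 fold change of -0.46. The mitotic kinase gene Aurkb (-0.85), the checkpoint gene Bub1b (-0.75) and the replication licensing genes Mcm5 (-0.74) and Mcm3 (-0.60) were lower, as the 4 members with the smallest adjusted p. Without genes that share sequence, 16 of the 23 members tested were lower. Endothelial (12 of 15), macrophage (10 of 12) and periocular mesenchyme (5 of 7) markers were higher in the same libraries. The set test of the cell cycle list had an adjusted p of 3.45e-10, and an adjusted p = 0.576 with an estimated correlation. Targets of p53 and apoptosis genes had 9 of 25 higher and 0 lower (9 and 1 adjusted over the list alone; set test adjusted p = 0.134). The higher count was 5 without cKO replicate 2 or 3 and with thinned reads, and 2 members were lower with RLE or TMM scaling, limma-voom, edgeR or correction for GC content and length, and 1 was lower without wild-type replicate 1. Among them Fas, a death receptor gene, rose by 1.5, Phlda3 by 1.28, Plk2 by 0.83 and Trp53inp1 by 0.80. Cdkn1a, a cell cycle inhibitor gene, had a log2 fold change of 0.45 (adjusted p = 0.0271), a call lost when any library other than wild-type replicate 3 was left out and with DESeq2.

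Genes of fibrosis and mesenchymal transition had 12 of 29 higher and 4 lower (12 and 4 adjusted over the list alone), with a set test adjusted p of 0.0249 and an adjusted p = 0.324 with an estimated correlation. Acta2 (ENSMUSG00000035783; chromosome 19, 34241090 to 34255590), which encodes smooth muscle actin, rose from 4.80 ± 0.105 to 44.4 ± 13.4 CPM (log2 fold change 2.92, adjusted p = 9.70e-07). Tagln, which encodes the actin-binding protein transgelin, rose by 2.75, with 66.4% of its words shared with other genes, and the membrane metalloproteinase gene Mmp14 rose by 1.43. Against this direction, Col6a3, a collagen VI chain, fell from 142 ± 11.3 to 38.9 ± 3.17 CPM (log2 fold change -1.84) and Thbs1, which encodes thrombospondin 1, fell by 1.36. Fn1, which encodes fibronectin, did not pass the test (-0.31, adjusted p = 0.150) and did pass it with TMM or RLE scaling. Tgfbi was called at 0.47 (adjusted p = 0.0296), a call lost without cKO replicate 1 or 2 or wild-type replicate 2 or 3, and with edgeR, DESeq2 and limma-voom. The set test of the list was lost when a mean of at least 5 CPM was asked for, and the lower count was 2 without wild-type replicate 1. Of the periocular mesenchyme markers, which share collagen genes with this list, 5 of 7 were higher and 1 lower in the same libraries.

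Basement membrane genes were split, with 7 of 29 higher and 9 lower (7 and 10 adjusted over the list alone; set test adjusted p = 0.324). The laminin chain gene Lama2 had a log2 fold change of -1.53 and Frem2 of -1.33, Npnt, which encodes the integrin ligand nephronectin, fell by 0.52, and Sparc rose by 0.47. TGF-β and BMP signalling genes had 11 of 27 higher and 2 lower (11 and 2 adjusted over the list alone; set test adjusted p = 0.0856). Id2, a BMP-responsive transcriptional regulator gene, rose by 1.08 and Bmpr1b by 0.78, while the ligand gene Bmp7 (-1.04) and Id3 (-0.52) fell. FGF and ERK feedback genes had 1 of 17 higher and 3 lower (1 and 3 adjusted over the list alone; set test adjusted p = 0.715). Dusp6 rose by 0.39, and Fgfr1 (-0.44), Spred2 (-0.38) and Etv5 (-0.34), with 26.4% of its words shared, fell. Correction for GC content and length gave 2 higher. Wnt signalling genes had 4 of 29 higher and 2 lower (3 and 1 adjusted over the list alone; set test adjusted p = 0.886), with Nkd1 at 0.56, Wls at 0.53, Fzd6 at 0.39 and Wnt7a at -0.64. The Wnt counts were unstable, with 4 lower under RLE or TMM scaling, limma-voom, DESeq2 and edgeR, 5 lower without wild-type replicate 1, 1 lower without cKO replicate 1 or 3 or wild-type replicate 2 or 3, and 7 higher without wild-type replicate 3 or with correction for GC content and length.

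Crystallin genes, which encode the main structural proteins of the lens, had 1 of 16 higher and 1 lower (1 and 1 adjusted over the list alone; set test adjusted p = 0.587). The lower count was 4 without cKO replicate 1, 2 without wild-type replicate 3 and 3 with DESeq2. Crygb rose by 0.45, with 32.9% of its words shared, and Cryba2 fell by 0.39. Cryaa (-0.08, adjusted p = 0.496; 13.6% of words shared), Crybb1 (-0.06, adjusted p = 0.671), Crybb3 (-0.23, adjusted p = 0.0515) and Cryba4 (-0.22, adjusted p = 0.0686) did not pass the test. Fiber differentiation genes had 3 of 22 higher and 7 lower (3 and 7 adjusted over the list alone), with a set test adjusted p of 0.0279 and an adjusted p = 0.576 with an estimated correlation. That set call was lost without cKO replicate 2 or wild-type replicate 2, and the counts were 1 higher with correction for GC content and length and 4 lower of 17 tested without genes that share sequence. Bfsp2, also listed as strain-variable, was at -5.32, while the other 21 members tested had a median of -0.13 and a lowest value of -0.75. No set test left out Bfsp2 alone, so the set call cannot be read as a fall of fiber genes in general. Besides Bfsp2, the cyclin-dependent kinase inhibitor gene Cdkn1c fell by 0.51, with 31.1% of its words shared, and the transcription factor gene Maf rose by 0.50 and Caprin2 by 0.42, the latter call lost with correction for GC content and length. Mip, which encodes the major intrinsic protein of fiber membranes and shares 57.1% of its words, had a log2 fold change of -0.21 (adjusted p = 0.0320), a call lost without cKO replicate 2 or 3 or wild-type replicate 2 or 3. Prox1, a fiber cell transcription factor gene, was at -0.05 (adjusted p = 0.633). Lens epithelium genes had 5 of 21 higher and 4 lower (5 and 4 adjusted over the list alone; set test adjusted p = 0.715), and 1 was lower without cKO replicate 1 or 3 or wild-type replicate 3. Clu rose by 0.64 and the E-cadherin gene Cdh1 by 0.46. Pax6 stood at 267 ± 29.9 CPM in cKO and 269 ± 14.4 CPM in wild type (adjusted p = 0.894). Foxe3 was called at -0.37 (adjusted p = 0.0424), with overlapping groups, and lost its call without cKO replicate 1 or 3 or wild-type replicate 1 or 3. Cell-cell junction genes had 3 of 23 higher and 6 lower (4 and 6 adjusted over the list alone; set test adjusted p = 0.351; 3 lower without cKO replicate 3), with Cdh4 at -0.68, the lens connexin gene Gja3 at -0.34 and Pvrl3 at 0.33.

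**Figure D3:**
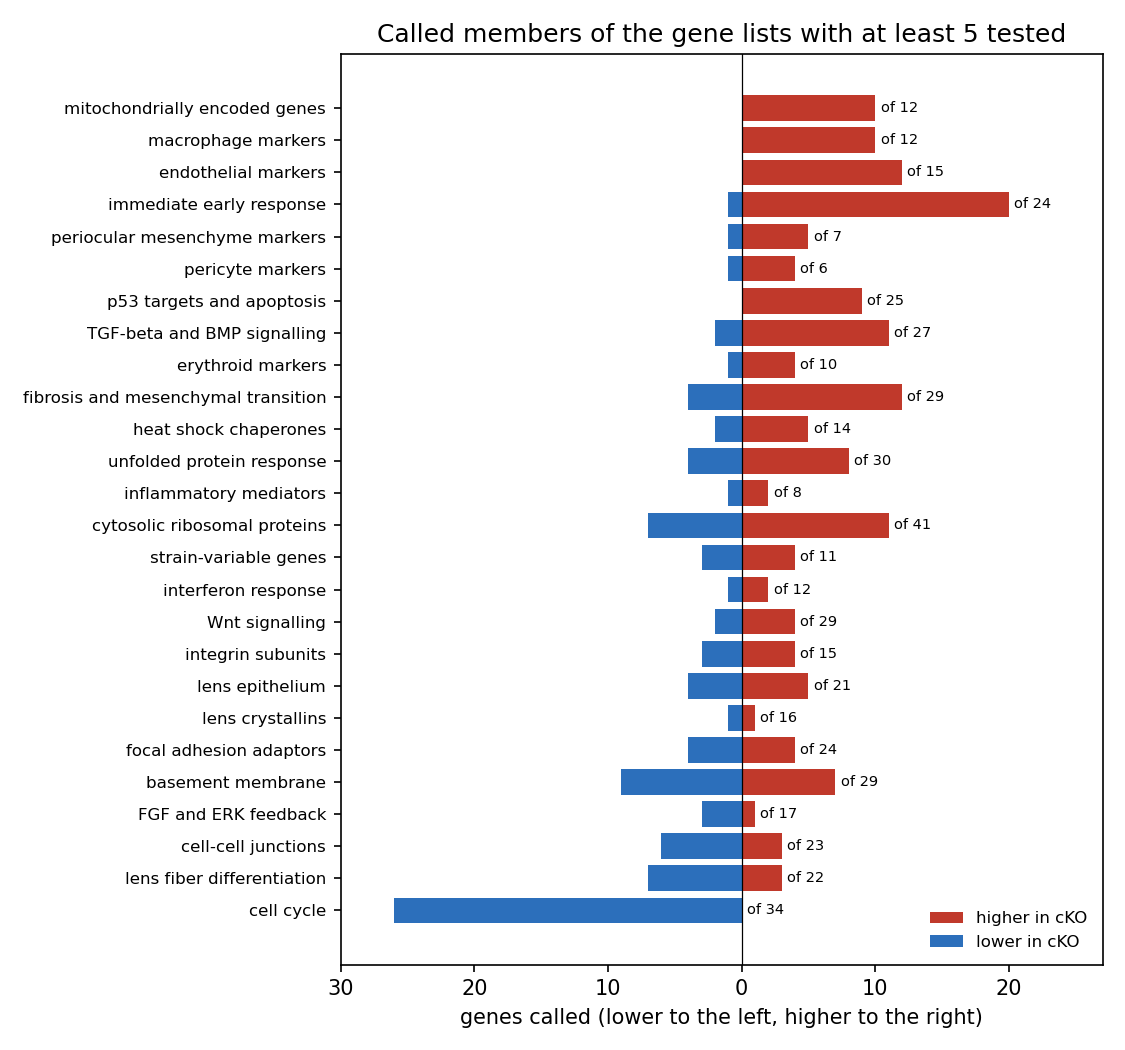
Number of called members of each gene list with at least 5 tested genes, with lower genes drawn to the left of 0, higher genes to the right, and the number tested beside each bar. Cell cycle genes had 26 of 34 lower, and immediate early genes 20 of 24 higher.

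Genes of the unfolded protein response had 8 of 30 higher and 4 lower (8 and 5 adjusted over the list alone; set test adjusted p = 0.886), with Ppp1r15a at 0.88, Vldlr at 0.42, Hyou1 at -0.52 and Pdia6 at -0.45. The balance of this list turned with the processing, to 5 higher and 8 lower with correction for GC content and length and 5 and 5 with edgeR, DESeq2 and limma-voom. It was 5 and 4 without cKO replicate 1, 3 and 4 without cKO replicate 3, and 4 and 4 without wild-type replicate 2. Heat shock chaperones had 5 of 14 higher and 2 lower (5 and 2 adjusted over the list alone; set test adjusted p = 0.617). Without genes that share sequence, 2 of the 7 tested were higher and 1 lower. Dnaja1 (0.53; 21.9% of words shared), Hspe1 (0.47; 32% shared) and Chordc1 (0.42) rose, and the constitutive chaperone gene Hspa8 fell from 450 ± 13.7 to 108 ± 5.33 CPM, with 47.3% of its words shared with other genes. Inflammatory mediators had 2 of 8 higher and 1 lower (2 and 1 adjusted over the list alone; set test adjusted p = 0.351), with the chemokine gene Cxcl12 at 3.49 CPM in cKO and 0.146 CPM in wild type. Of these mediators, 0 were higher without cKO replicate 2 or 3, 1 was higher without cKO replicate 1 or wild-type replicate 2, and 0 were lower without cKO replicate 2 or any wild-type replicate. Interferon response genes had 2 of 12 higher and 1 lower (2 and 1 adjusted over the list alone; set test adjusted p = 0.842), with Xaf1 at 1.14 and Rsad2 at -1.21, and 0 were higher without cKO replicate 1 or 3 and 1 without cKO replicate 2 or wild-type replicate 2 or 3. Of 4 keratins tested, Krt10 (0.71) and Krt19 (0.69) were higher and Krt18 (-0.61; 12% of words shared) was lower, a call lost without cKO replicate 3 or wild-type replicate 2, with the same counts adjusted over the list alone, and 1 was higher when any 1 of the cKO replicates was left out. Cytosolic ribosomal protein genes had 11 of 41 higher and 7 lower (12 and 7 adjusted over the list alone; set test adjusted p = 0.875), with Rpl10a at 0.64, Rpl6 at -0.65, Rpl37 at -0.61 and Rpl8 at -0.50. Shared words made up 20.7% of Rpl10a, 31.8% of Rpl6 and 14.6% of Rpl37, and without genes that share sequence 2 of the 6 tested were higher and 2 lower. Correction for GC content and length gave 12 lower. Mitochondrially encoded genes had 10 of 12 higher and 0 lower (10 and 0 adjusted over the list alone), with mt-Nd3 at 1.85, although 100% of its words are shared, and mt-Atp8 at 1.23. Correction for GC content and length took the median log2 fold change from 0.743 to 0.427 and gave 8 higher and 1 lower, and without genes that share sequence 3 of the 3 members tested were higher. Their set test had an adjusted p of 3.79e-06, and an adjusted p = 0.576 with an estimated correlation. They took 1.54% to 1.81% of reads in cKO and 0.87% to 1.19% in wild type.

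Of the cell types other than lens that a dissected pool can hold, some had markers higher in cKO. Endothelial markers had 12 of 15 higher and 0 lower (12 and 0 adjusted over the list alone; set test adjusted p = 1.93e-05, adjusted p = 0.576 with an estimated correlation), with Tek, the angiopoietin receptor gene, at 1.05 and Cdh5 at 0.63. Macrophage markers had 10 of 12 higher and 0 lower (12 and 0 adjusted over the list alone; set test adjusted p = 2.07e-05, adjusted p = 0.402 with an estimated correlation), with C1qa at 1.22 and Cx3cr1 at 1.20, each under 5 CPM. At a mean of at least 5 CPM, 0 macrophage markers were left to test. Periocular mesenchyme markers had 5 of 7 higher and 1 lower (5 and 1 adjusted over the list alone; set test adjusted p = 0.0104, adjusted p = 0.324 with an estimated correlation), with Eya2 at 1.68 and Foxc1 at 0.86, and the set call was lost without cKO replicate 1, while 0 were lower without cKO replicate 1 or 2 or wild-type replicate 2 or 3. Pericyte markers had 4 of 6 higher and 1 lower (4 and 1 adjusted over the list alone; set test adjusted p = 0.0726), with Rgs5 rising from 41.4 ± 2.84 to 87.3 ± 6.93 CPM, and 0 lower without cKO replicate 3. Erythroid markers had 4 of 10 higher and 1 lower (4 and 1 adjusted over the list alone; set test adjusted p = 0.0279, adjusted p = 0.576 with an estimated correlation), with the globin gene Hbb-bs at 1.21 and 48.8% of its words shared, and the set call was lost without cKO replicate 1. Of these, 0 were lower without cKO replicate 2 or wild-type replicate 1 or 2, and 2 were higher with limma-voom. Of 3 retina markers Hes5 was higher, at 0.38, with 26.3% of its words shared, and lost its call without cKO replicate 1, 2 or 3 or wild-type replicate 1 or 2. Of 3 pigment cell markers Oca2 was lower, at -0.66. Neither of the 2 skeletal muscle markers, Mylpf (0.02) and Ttn (0.00), nor Perp (0.00), the tested surface ectoderm marker, passed limma's test. Strain-variable genes had 4 of 11 higher and 3 lower (6 and 3 adjusted over the list alone; set test adjusted p = 0.886), with Wdfy1 at 0.46 and Pde6b at -0.73, and 2 were higher without cKO replicate 3 or wild-type replicate 2 and 1 lower without wild-type replicate 2. The set test asks for a shared direction, and the strain-variable genes went both ways, so its adjusted p does not decide about strain. Fry gave this list an adjusted p of 0.00193. Over all tested genes 36.9% were called. Because the strain differs with genotype, differences between these libraries cannot be assigned to genotype alone.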

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

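Added after seeing the data were the tests with edgeR on recovered reads, TMM-scaled CPM, thinned reads, no chromosome 8 and no genes sharing sequence. Itgb1 stayed lower and called in each alternative that kept chromosome 8 in the test, with log2 fold changes of -0.84 to -0.66, and leaving out a library gave -0.77 to -0.66. The counts of genes higher (1879 to 2916) and lower (1515 to 2511) stayed within 1.5 times the reported counts in the alternatives other than leaving out a library. Their balance moved with scaling. Of the called genes 56.8% were higher in the main test, against 50.3% with RLE, 50.5% with TMM and 47.7% with DESeq2. The share was 56.7% with a pseudocount of 0.1 and 55.8% with thinned reads. Leaving out a library gave 1714 to 2400 genes higher, 1322 to 1922 lower, 147 to 208 higher at least 2-fold, 80 to 103 lower at least 2-fold and 7 to 10 lists past the set test. Counts of changes of at least 2-fold moved more: 353 higher and 159 lower with a pseudocount of 0.1, 346 and 182 with limma-voom, 398 and 226 with DESeq2 and 427 and 212 with edgeR. A smaller pseudocount shrinks low genes less by construction, and for the other tests the cause was not tested. Asking for a mean of at least 5 CPM tested fewer genes (9531) and left 105 higher at least 2-fold and 5 lists. The 9 lists past the set test became 0 with an estimated correlation and 14 with fry, which tests another hypothesis. Of 140 named genes, 18 lost their call in at least 1 alternative, 6 gained one, and 0 changed sign while called. Besides the loss of each set call with an estimated correlation, the erythroid, fibrosis, periocular mesenchyme and fiber differentiation lists lost theirs in at least 1 other alternative, and the macrophage list had 0 members to test at a mean of at least 5 CPM. Thinned to equal depth, the libraries gave 2198 genes higher and 1738 lower. Depth limits low genes most, since 1 read was worth 0.0998 CPM in the smallest library.

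With the replicate number as a block (a paired fit), 2916 genes were higher and 2249 lower, 194 and 97 at least 2-fold, and 9 lists passed. Deviations of same-numbered samples correlated at 0.327, -0.034 and 0.147, and not every sample correlated best with its own number. With 3 samples per group this cannot exclude pairing, and the paired fit called 5165 genes against 4403 in the main test. No label states that the numbers pair the samples. Itgb1 kept its call under the replicate block.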

Other observations

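The 3 gene groups of the first paragraph, the strain tests, the test of other tissues and the test of handling stress were chosen only after the result was seen. Genes of glycolysis were lower in cKO lenses, with 15 of 21 lower and 1 higher and a median log2 fold change of -0.41. Ldha, which encodes lactate dehydrogenase A, fell from 360 ± 9.02 to 216 ± 21.5 CPM, and the glucose transporter gene Slc2a1 fell by 0.64, while the neuronal enolase gene Eno2 rose by 0.71. Annexin, S100 and caveola genes had 11 of 15 higher and 0 lower, with Anxa2 rising from 23.7 ± 3.08 to 92.3 ± 15.3 CPM and Ahnak by 1.86. Endothelial (12 of 15), macrophage (10 of 12) and periocular mesenchyme (5 of 7) markers were higher in the same libraries. Imprinted genes went both ways, with 7 of 20 higher and 3 lower, and did not pass camera (adjusted p = 0.239 over the 3 groups). Among them the noncoding RNA gene H19 rose from 3702 ± 328 to 8307 ± 476 CPM and Igf2 by 0.79, while Mest had a log2 fold change of -0.39. Camera gave adjusted p values of 1.27e-07 for glycolysis and 1.19e-05 for annexins, S100 proteins and caveolae, each with an adjusted p = 0.0762 with an estimated correlation. These groups were written after the values of single genes, such as Anxa2, Ahnak, Ptrf, Ldha and H19, had been seen, so their p values are not independent evidence.

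Mt2, the neighbouring metallothionein gene, was at 0.329 ± 0.163 CPM in cKO and 0.212 ± 0.0437 CPM in wild type, while Mt1 was at 242 CPM in cKO. Bfsp1, the filament partner of Bfsp2, was at 4320 ± 566 CPM in cKO and 4870 ± 197 CPM in wild type (limma adjusted p = 0.149), and the other 21 tested genes of the fiber list had a median log2 fold change of -0.13. The Y-linked genes Ddx3y (0.92), Eif2s3y (1.03) and Uty (0.57) were higher in cKO, while Kdm5d (0.19, adjusted p = 0.364 by limma) and Xist (-0.26, adjusted p = 0.341 by limma) did not pass the test.

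Chromosome 8, which carries Itgb1, held 23 genes changed at least 2-fold among 632 tested (3.64%), against 265 of 11225 (2.36%) on the other chromosomes. DNA of the donor strain carried with the floxed allele may account for such genes, but the odds ratio was 1.56 (95% interval 0.965 to 2.42; Fisher's exact p = 0.0465, 0.186 adjusted over 20 chromosomes). Such DNA would be densest within 20 Mb of Itgb1. There 0 of 132 genes changed at least 2-fold, against 23 of 500 on the rest of the chromosome (Fisher's exact p = 0.0071). The changed genes were therefore not concentrated around Itgb1. That contrast rests on the rate outside the window, so it cannot decide about donor DNA on the rest of the chromosome. For strain haplotypes elsewhere, 33 pairs of such genes within 1 Mb moved in opposite directions, against a median of 27 in 1000 random draws (95th percentile 38, permutation p = 0.21). Pairs that moved in the same direction numbered 44, against a median of 35 (95th percentile 47, permutation p = 0.11). Both counts lay above the median and below the 95th percentile, so the draws cannot decide. Strain variants and genotype cannot be told apart in this design, because each cKO library has a mixed background.

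Genes with copies elsewhere were over-represented among changes of at least 2-fold, with 79 of 2317 genes that share at least 10% of their words (3.41%) against 214 of 9557 others (2.24%). The odds ratio was 1.54 (95% interval 1.17 to 2.01; Fisher's exact p = 0.00167), which is what reads shared between near-identical genes may give. Reads moved from a gene to its copies would leave opposite changes, and 14 of the 67 such genes with a copy in the files (20.9%, exact 95% interval 11.9% to 32.6%) had copies that changed oppositely by at least 50% of the gene's own change, which leaves this open. The gene model Gm26825, at 50.8 CPM in cKO and listed at 0 in each wild-type library, meets this against Hspa8, but Hspa8 does not, since it fell by 342 CPM and its copies rose by 50.8 CPM. A biological change of these genes remains possible and was not tested.

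Egr1, Nab1, Nab2, Acta2, Tagln and Itgb8 rose together with markers of other tissues. More vascular, mesenchymal or macrophage tissue in the cKO pools could raise them. Values were compared at a pseudocount of 0.1, which shrinks low markers less. The highest median plus SD of the endothelial, pericyte, macrophage and periocular mesenchyme lists was 2.1, and the highest single marker was the periocular gene Eya2 (2.67). Acta2 (3.14), Tagln (3.29), Egr1 (3.42) and Nab2 (3.74) rose by more than either, while Nab1 (1.59) and Itgb8 (2.36) lay below Eya2. The bound and the grouping of genes were set after main values were known, and the genes were picked as strong risers, which favours a gap. The values show only that these 4 genes rose by more than the listed markers. Whether such tissue was the whole source stays open for all 6 genes. Smooth muscle would bring its other transcripts, which were compared at a pseudocount of 1. Its 4 tested markers of 10 had a median of 0.355, against 2.75 for Tagln. Of these 2 were higher, Des (0.66, from 1.12 to 2.38 CPM) and Synpo2 (0.50, from 4.44 to 6.71 CPM), and 0 lower. For the tested markers this argues against smooth muscle as the whole source. The others, such as Myh11 (0.609 CPM in cKO and 0.653 CPM in wild type), were too low to test. Handling stress before RNA extraction stays open, since Fos, Junb, Ier2, Atf3 and Jun had a median of 1.08. It would raise Hspa1a and Hspa1b too, and neither mean was higher in cKO, though both genes were too low to test. Hspa1a was at 0.0404 CPM in cKO and 0.116 CPM in wild type, and Hspa1b at 0.334 and 0.395 CPM. A response to the conditional knockout is a further hypothesis that this design cannot part from strain or handling.

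With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 4403 called genes, with 0 as the highest of the other splits and 1 of 10 splits as large. It gave 294 changes of at least 2-fold, again with 0 as the highest other and 1 of 10 as large. For gene lists past the set test the real split gave 9 and the highest other 11, with 3 of 10 splits as large.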
